A study of Mus musculus with 6 samples.

How the data were processed

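Bulk RNA sequencing was compared between forebrains of 3 wt and 3 Dyrk1a heterozygous mouse embryos at embryonic day 15.5, with groups and replicate numbers taken from the sample titles. The deposited table holds raw counts per Ensembl gene, with 1 column per library; whole numbers and unequal column totals were checked. Per the submitters' processing notes, reads were made with bcl2fastq 2.17.1.14, aligned to GRCm38/mm10 with HISAT2, handled with SAMtools 1.9 and counted with HTSeq 0.9.1. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on either strand may have been counted together. The labels name both polyadenylated RNA and a total-RNA kit with ribosomal depletion, and which was used is not settled by them; RNAs without a poly(A) tail, such as 7SK, were present in the counts. Of 33084 gene identifiers 32888 were given a symbol from the GENCODE M21 annotation on GRCm38 and 196 were left without.

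Totals ran from 18699434 to 32865708 counts per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its defaults, which left 19403, and libraries were scaled by TMM (factors 0.9944 to 1.0034). Genotype was the only term of the model, fitted by edgeR's quasi-likelihood method, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.131. Log2 fold changes are heterozygote minus wt, and their standard errors and 95% intervals come from the quasi-likelihood F statistic. Standard errors of list medians were taken over the genes of a list as if independent, and do not measure spread between embryos. Single-gene CPM and list scores were also compared by exact 2-sided permutation of the 6 libraries, whose smallest p is 0.1. Single-gene values carry the SD over 3 libraries; reads are not independent molecules, so counting error alone understates the spread.

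The test, the gene lists, the rule for naming genes and the alternative settings were set before the data were examined. The rule names Dyrk1a; then up to 12 genes per direction past the threshold, with a mean of at least 1 CPM and no overlap between genotypes, filled to 5 per direction by lowest unadjusted p; the 4 members of lowest unadjusted p in each called list and 2 in each other list; and Ttc3, Vps26c and Kcnj6 near Dyrk1a. Genes named outside the rule are members that passed adjusted over the list alone, genes that check sex, and genes of the closing section, which were picked after their values were seen; a few members that the rule names are not reported here. Fixed lists of cell types, pathways and chromosome 16 neighbours, 43 in all, were tested by camera with a preset inter-gene correlation of 0.01 and at least 5 tested members, adjusted over 42 lists. The remaining list, of X-inactivation and Y-linked genes, served as a check of sex and was not counted. Camera with an estimated correlation and fry were run beside it.

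On data simulated with the dispersions and depths of these libraries, with 200 changed genes, 30% of 1.5-fold, 70% of 2-fold, 90% of 3-fold and 92% of 4-fold changes were called, and 13 of 154 called genes were unchanged. In that simulation 5 of 5 lists shifted 1.2-fold were called by camera and 0 of the unshifted ones; simulated genes varied independently, so this does not test camera against correlation between genes. Columns were checked for duplicates: counts of library pairs differed by a chi-square per degree of freedom of 4.86 to 32.4, so no library was a copy of another. The alternative settings covered size factors, test, low-count filter, robust fitting, a replicate block, library sizes without mitochondrial and globin genes, thresholds, list tests, list content and leaving out each library. Added after the data were seen were a term for the pair of libraries with the most 7SK, RNase P and RNase MRP RNA, the 4 other libraries alone, counts thinned to the smallest total, and removal of length and GC trends. All 6 libraries were used in every main comparison.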

Results

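Forebrain RNA was sequenced from mouse embryos at embryonic day 15.5, from 3 wild-type (wt) and 3 heterozygous Dyrk1a mutant samples that the labels call biological replicates. Dyrk1a encodes a dual-specificity kinase of brain growth and cell cycle exit. The comparison asks which forebrain transcripts differ when a single copy of Dyrk1a is inactive. The deposited values were raw counts for 33084 genes, of which 30785 had at least 1 count and 19403 were tested. The wt libraries held 32865708, 25270710 and 27861000 counts, and the heterozygote libraries 20682150, 25012356 and 18699434. A pair of libraries, wt replicate 3 and heterozygote replicate 2, stood apart from the 4 others on the first principal component, which held 34.9% of the variance. In these the non-coding RNAs 7SK, RNase P RNA and RNase MRP RNA took 4.46% and 4% of counts, against 2.56% to 3.01% in the 4 others. The pair held 1 library of each genotype, so values within the pair and within the 4 others are given for Rfx5, Ptgds, Dyrk1a and the called lists. The Y-linked gene Ddx3y was present in all 6 libraries, at 47.8 to 64.1 CPM (counts scaled by effective library size), and Xist, the RNA that silences an X chromosome, at 0.36 to 1.07 CPM.

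**Figure D1:**
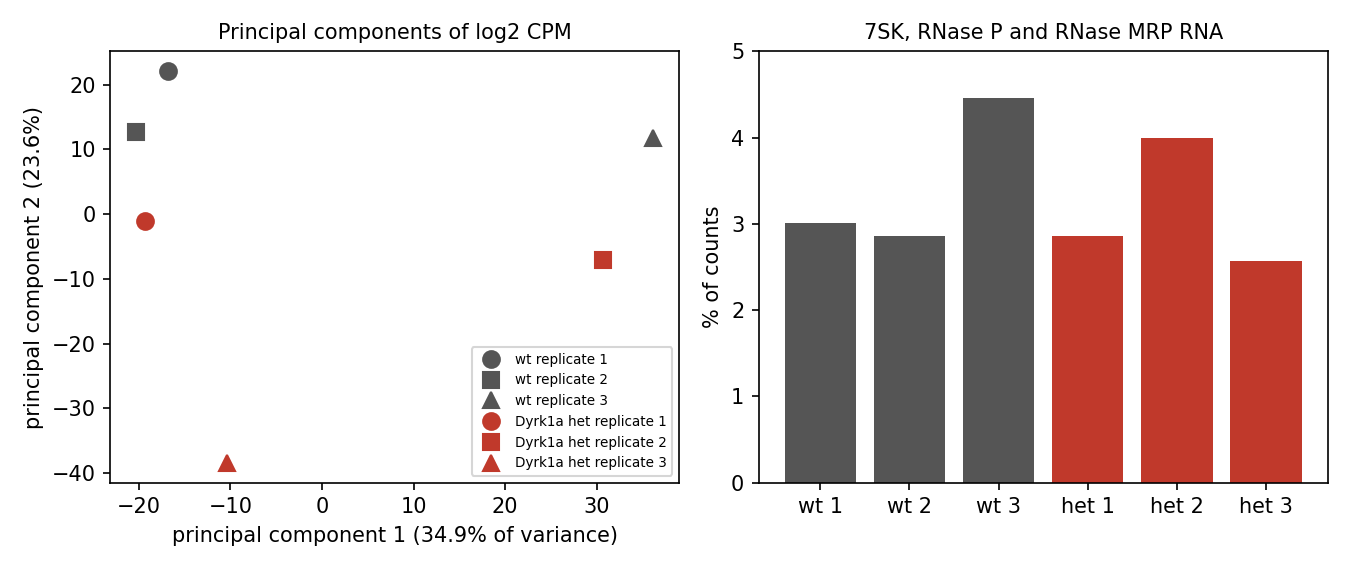
Left, the 6 libraries on principal components 1 and 2 of log2 CPM (34.9% and 23.6% of variance), coloured by genotype. Right, the percentage of counts taken by 7SK, RNase P and RNase MRP RNA in each library; wt replicate 3 (4.46%) and heterozygote replicate 2 (4%) lie above the other 4.

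Single-gene differences between the genotypes were few, and small differences ran through lists of genes of a cell type or pathway, in camera calls that did not hold with an estimated correlation between genes or with fry. In the heterozygotes Rfx5 was 1.82-fold of wt and Ptgds 0.449-fold. All 45 tested genes of G2 and M phase and all 32 of S phase were higher in heterozygotes, with median log2 fold changes of 0.35 and 0.28. Of 71 synaptic genes 64 were lower, with a median of -0.17, and genes of meninges, oligodendrocyte precursors and microglia were mostly lower. Dyrk1a itself was at 0.868 of the wt level and did not pass the test.

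Rfx5 rose and Ptgds fell, the 2 genes that passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Rfx5 (ENSMUSG00000005774, GRCm38 chromosome 3, 94954075 to 94961561), a subunit of the complex that binds promoters of major histocompatibility class II genes, went from 32.02 ± 1.47 CPM in wt to 58.2 ± 1.44 (SD, n = 3 per genotype). Its log2 fold change was 0.86 (SE 0.074; edgeR, Benjamini-Hochberg adjusted p = 0.022), and it was higher in 3 of 3 heterozygotes than in any wt library. Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046), the prostaglandin D synthase abundant in the leptomeninges, went from 32.6 ± 2.33 to 14.7 ± 1.57 CPM (SD, n = 3 per genotype). Its log2 fold change was -1.16 (SE 0.109; edgeR, Benjamini-Hochberg adjusted p = 0.0238), and all 3 heterozygotes lay below all wt libraries. For either gene the exact 2-sided permutation p over CPM was 0.1, the smallest that 3 against 3 libraries allow. Within the pair of libraries and within the 4 others, log2 CPM differed by 0.92 and 0.83 for Rfx5 and by -1.26 and -1.10 for Ptgds. Both calls were lost without wt replicate 1 (edgeR adjusted p 0.146 for Rfx5 and 0.171 for Ptgds), wt replicate 2 (0.157 for both), heterozygote replicate 1 (0.219 and 0.308) or heterozygote replicate 3 (0.137 for both). In those fits log2 fold changes were 0.83 to 0.90 and -1.23 to -1.09. In those 4 fits 0 genes passed edgeR's test (790, 1200, 1554 and 818 at an unadjusted p under 0.05), and without heterozygote replicate 2 there were 5. With replicate number as a block 0 passed, with adjusted p values from edgeR of 0.245 and 0.19 for these genes. A B230398E01Rik transcript, with 29 counts over all libraries, overlaps Rfx5 on the opposite strand.

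At an unadjusted p under 0.05 there were 1528 genes, 634 higher and 894 lower, against 970 that chance would give. The genotypes did not overlap in 2720 genes, 14% of those tested, where chance gives 10%. DESeq2 called 27 genes at an adjusted p under 0.05 (13 higher, 14 lower), both edgeR genes among them; edgeR with no low-count filter called 4, and edgeR with a term for the pair of libraries, or on the 4 others alone, called 6 each. Of the higher genes that missed edgeR's threshold, those with the lowest p were Ucp2, an uncoupling protein of the mitochondrial inner membrane (log2 fold change 0.89, SE 0.106; 8.38 against 15.5 CPM), Ypel2 (0.52, SE 0.088), the spindle assembly factor Tpx2 (0.45, SE 0.081) and the stress-inducible sestrin Sesn2 (0.86, SE 0.159). Of the lower genes they were Dio2, the deiodinase that activates thyroid hormone (-1.22, SE 0.162; 4.37 against 1.87 CPM), Lmo7 (-0.84, SE 0.123; 39.9 against 22.3 CPM), the copine Cpne4 (-0.68, SE 0.105) and Ache, acetylcholinesterase (-0.69, SE 0.13; 10.8 against 6.65 CPM). All 8 were among the DESeq2 calls, and edgeR with a term for the pair of libraries also called Ucp2 (Benjamini-Hochberg adjusted p = 0.0192) and Lmo7 (0.00893). Dnajb13, with 251 counts, overlaps Ucp2 on the opposite strand.

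Dyrk1a (ENSMUSG00000022897, chromosome 16, 94570010 to 94695517) had 174 ± 12.9 CPM in wt and 151 ± 6.28 CPM in heterozygotes (SD, n = 3 per genotype). The log2 fold change was -0.20 (SE 0.079, 95% interval -0.38 to -0.024; edgeR, Benjamini-Hochberg adjusted p = 0.59), and the exact 2-sided permutation p was 0.1. The interval runs from 0.766 to 0.984 of the wt level. All 3 heterozygotes, at 149, 147 and 158 CPM, lay below the wt libraries, at 177, 186 and 160 CPM. The log2 CPM difference was -0.13 within the pair of libraries and -0.24 within the 4 others. The labels do not say which part of the gene was deleted, so counts over the whole gene are a weak check of genotype. Gm15971, on the same strand, overlaps Dyrk1a and had 688 counts over all libraries.

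**Figure D2:**
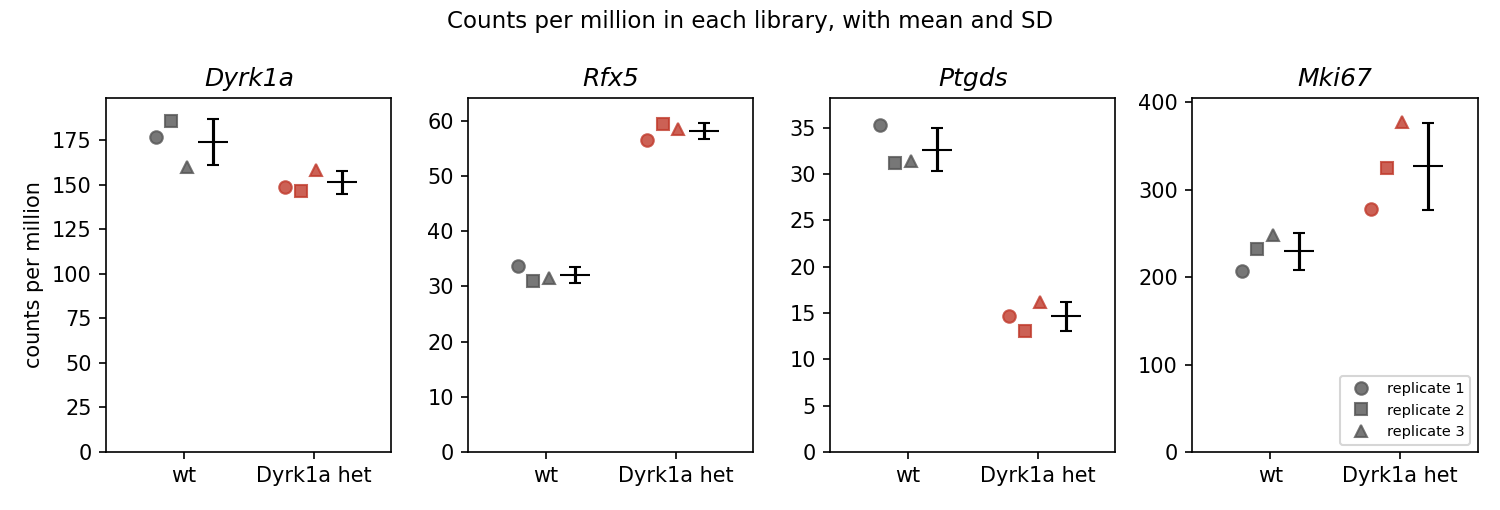
CPM of Dyrk1a, Rfx5, Ptgds and Mki67 in each library, 3 wt and 3 heterozygous, with the mean and SD of each genotype at the side. In each panel the genotypes do not overlap; Rfx5 averaged 32.02 CPM in wt and 58.2 in heterozygotes, and Ptgds 32.6 and 14.7.

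Neighbouring genes on chromosome 16 went both ways. Of 72 tested genes within 5 Mb of Dyrk1a, 39 were higher and 33 lower, with a median log2 fold change of 0.012. By edgeR 0 of them passed, over all genes or over the window alone, and 7 were at an unadjusted p under 0.05; DESeq2 called none of those in the fixed list of neighbours. That list had 13 of 30 members higher and a median of -0.019 (camera adjusted p = 0.839), with the lowest p in the secretase Bace2 (-0.89, SE 0.288) and the transcription factor Sim2 (0.82, SE 0.34). Ttc3 was at 1500 and 1514 CPM and Vps26c at 55.5 and 55.9 CPM in wt and heterozygotes, and the potassium channel gene Kcnj6 at 8.92 and 7.38 CPM (log2 fold change -0.27, SE 0.119).

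Proliferation genes were higher as lists in heterozygotes. Of the G2 and M phase list, 45 of 45 members were higher, with a median log2 fold change of 0.35 (camera, Benjamini-Hochberg adjusted p = 1.72e-37; adjusted p = 0.239 with an estimated correlation). Of its members 34 passed adjusted over the list alone and 0 over all genes by edgeR, with 38 at an unadjusted p under 0.05; DESeq2 called 4. Tpx2, the mitotic kinase Ttk, the kinetochore protein Cenpf and the proliferation marker Mki67 had log2 fold changes of 0.45, 0.53, 0.42 and 0.51 (SE 0.081 to 0.118), and Mki67 was at 229 ± 20.8 CPM in wt and 327 ± 49.8 in heterozygotes (SD, n = 3 per genotype). For S phase and DNA replication, 32 of 32 were higher, with a median of 0.28 (camera adjusted p = 1.8e-23; adjusted p = 0.239 with an estimated correlation), 22 passing adjusted over the list alone and 0 over all genes (edgeR; 26 at an unadjusted p under 0.05; none by DESeq2). Among these were the ribonucleotide reductase subunit Rrm2 (0.40), the origin recognition subunit Orc1 (0.60), the uracil glycosylase Ung (0.39) and thymidylate synthase, Tyms (0.28). Mean log2 CPM of the G2 and M list differed by 0.28 within the pair of libraries and 0.36 within the 4 others, and that of the S phase list by 0.19 and 0.34. The G1 list differed by 0.044 and 0.18, and the histone list by 0.17 and 0.42. Of 21 G1 cyclins, kinases and inhibitors, 18 were higher (median 0.15; camera adjusted p = 0.00115; adjusted p = 0.402 with an estimated correlation), with 0 adjusted over the list alone or over all genes by edgeR, 4 at an unadjusted p under 0.05 and none by DESeq2. E2f2, E2f1, Rbl1 and Cdkn2c had 0.35, 0.29, 0.35 and 0.35 (SE 0.093 to 0.137; Rbl1 0.22 to 0.47 with 1 library left out), and without heterozygote replicate 3 the list was at 0.033 and lost its call. Of 58 genes in the histone cluster list, most of them transcribed in S phase, 56 were higher (median 0.27; camera adjusted p = 3.24e-09; adjusted p = 0.464 with an estimated correlation). None passed adjusted over the list alone or over all genes, by edgeR or DESeq2, and 2 were at an unadjusted p under 0.05: H1f0 (0.25, SE 0.083), a replacement linker histone that lies outside the clusters and is not tied to S phase, and Hist1h2br (-2.15, SE 0.717). Next were Hist1h1b (0.24) and Hist1h4n (1.16). Counts were low for Hist1h2br (1.01 against 0.219 CPM) and Hist1h4n (0.531 against 1.13 CPM). With 1 library left out Hist1h2br ran from -2.74 to -1.18, Hist1h1b from 0.14 to 0.34 and Hist1h4n from 0.62 to 2.16. The wt libraries spread widely in the histone score, at -0.56, 0.16 and 0.40, with an exact permutation p of 0.4. The histone median was 0.024 with no call without wt replicate 1, 0.52 without wt replicate 3 and 0.14 without heterozygote replicate 2.

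Lists of progenitors, Notch and hedgehog signalling and neural chromatin regulators were also called higher. Of 22 genes of intermediate progenitors, 19 were higher, with a median log2 fold change of 0.14 (camera adjusted p = 8.29e-06; adjusted p = 0.278 with an estimated correlation). The lowest p values were those of Rhbdl3 (0.43, SE 0.109), the antiproliferative gene Btg2 (0.36), the proneural factor Neurog2 (0.36) and Eomes, the T-box marker of these cells (0.26, SE 0.08; 69.9 against 83.4 CPM). Of 32 genes of apical progenitors 21 were higher, with a median of 0.15 (camera adjusted p = 0.00369; adjusted p = 0.417 with an estimated correlation). The Notch effector Hes1 (0.48, SE 0.118), Pax6 (0.29) and Ttyh1 (0.25) were higher, and the matrix protein tenascin C, Tnc, was lower (-0.55, SE 0.163). Notch signalling genes were higher in 20 of 27 cases, with a median of 0.12 (camera adjusted p = 0.00115; adjusted p = 0.464 with an estimated correlation), Hes1 again leading, then Hes5 (0.31), the ligand gene Dll1 (0.33) and Mfng (0.27). In the list of REST and chromatin regulators of neural genes, 29 of 32 were higher, with a median of 0.12 (camera adjusted p = 2.27e-06; adjusted p = 0.239 with an estimated correlation): the corepressor Rcor2 (0.30, SE 0.075), the remodeller Chd7 (0.30), the repressor Rest itself (0.29) and Actl6a (0.29). Of 18 Sonic hedgehog genes 13 were higher, with a median of 0.13 (camera adjusted p = 0.0358; adjusted p = 0.495 with an estimated correlation), among them Gli3 (0.32, SE 0.103), Cdon (0.19), Gas1 (0.31) and Boc (0.23). With 1 library left out Gli3 ran from 0.19 to 0.38, Gas1 from 0.18 to 0.41 and Boc from 0.14 to 0.34. In these 5 lists 0 members passed adjusted over the list alone or over all genes by edgeR, and DESeq2 called none. At an unadjusted p under 0.05 were 9, 10, 7, 7 and 2, and 1 of these was lower in each list but the hedgehog list. The lists share members, so their calls and counts are not separate. Hes1 and Hes5 are in the apical and Notch lists. Dll1 and Mfng are in the intermediate progenitor and Notch lists, and Cdon is in the apical and hedgehog lists. Within the pair of libraries and within the 4 others, intermediate progenitor scores differed by 0.12 and 0.23, and apical scores by 0.057 and 0.11. Notch scores differed by 0.064 and 0.13, REST scores by 0.10 and 0.13, and hedgehog scores by 0.044 and 0.067. The intermediate progenitor median was 0.23 without heterozygote replicate 2, and the REST median 0.082 without heterozygote replicate 3. The apical call was lost without wt replicate 1 (0.083) or heterozygote replicate 2 (0.087), and that median was 0.097 without heterozygote replicate 3. The Notch median was 0.059 without wt replicate 2, 0.19 without heterozygote replicate 1 and 0.058 without heterozygote replicate 3. The hedgehog call was kept without heterozygote replicate 1 and lost without wt replicate 1 (0.10), wt replicate 2 (0.11), wt replicate 3 (0.11), heterozygote replicate 2 (0.13) or heterozygote replicate 3 (0.049), and in thinned counts (0.13).

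Synaptic genes and genes of striatal and cortical projection neurons were lower as lists. Of 71 synaptic genes, 64 were lower and 7 higher, with a median log2 fold change of -0.17 (camera adjusted p = 2.73e-15; adjusted p = 0.239 with an estimated correlation). The synaptic vesicle protein Sv2b (-0.37, SE 0.086), the glutamate receptor subunit Grin3a (-0.34) and the kinase Camk2b (-0.39, SE 0.097; 196 against 150 CPM) were among those with the lowest p. Synaptic scores differed by -0.085 within the pair of libraries and -0.22 within the 4 others, and striatal scores by -0.16 and -0.22. Deep-layer scores differed by -0.16 and -0.12, and upper-layer scores by -0.074 and -0.13. Of 26 genes of striatal projection neurons 20 were lower, with a median of -0.14 (camera adjusted p = 0.000106; adjusted p = 0.239 with an estimated correlation), and the median was -0.22 without wt replicate 3. Among those with the lowest p were the opioid receptor Oprm1 (-0.50, SE 0.129), Rgs9 (-0.44) and Tac1, the substance P precursor (-0.38). Deep-layer cortical neuron genes were lower in 13 of 22 cases, with a median of -0.089 (camera adjusted p = 0.00894; adjusted p = 0.247 with an estimated correlation), led by Lmo7, then Ccn2 (-0.80), Crym (-0.52) and Ldb2 (-0.24). Upper-layer genes were lower in 13 of 20 cases, with a median of -0.052 (camera adjusted p = 0.0132; adjusted p = 0.239 with an estimated correlation), with Gucy1a1 (-0.41), Rorb (-0.33) and Mef2c (-0.45) among those with the lowest p. Of the 22 deep-layer genes 9 were higher, among them Sox5 (0.19), Bcl11b (0.04), Tbr1 (0.025) and Fezf2 (0.002), the last 3 near 0. Of the 20 upper-layer genes 7 were higher, among them Lhx2 (0.27), and Cux1 (-0.007) and Cux2 (-0.026) were near 0. Adjusted over the list alone, 1 deep-layer gene, Lmo7, and 1 upper-layer gene passed edgeR, and none of the synaptic or striatal genes did. Over all genes 0 members of the 4 lists passed edgeR's test, and DESeq2 called Lmo7. At an unadjusted p under 0.05 were 26, 8, 5 and 5, of which 1 deep-layer and 1 upper-layer gene were higher. The deep-layer call was lost without heterozygote replicate 2 (-0.058) and the upper-layer call without wt replicate 2 (-0.059). The upper-layer median was -0.091 without wt replicate 1, -0.087 without wt replicate 3 and -0.09 without heterozygote replicate 2.

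Lists of several other cell types were called lower. In the meninges and fibroblast list 38 of 44 were lower, with a median log2 fold change of -0.16 (camera adjusted p = 2.99e-10; adjusted p = 0.239 with an estimated correlation). Ptgds, Postn (-0.53, SE 0.114), the collagens Col6a3 (-0.49, SE 0.118) and Col1a2 (-0.32, SE 0.08; 154 against 124 CPM) and the retinoic acid synthase Aldh1a2 (-0.52) passed edgeR adjusted over the list alone, and Ptgds alone over all genes. Meningeal scores differed by -0.24 within the pair of libraries and -0.20 within the 4 others, and precursor scores by -0.17 and -0.40. Microglial scores differed by -0.09 and -0.28, pericyte scores by -0.17 and -0.11, and erythroid scores by -0.058 and -0.03. Of 19 genes of oligodendrocyte precursors 15 were lower, with a median of -0.29 (camera adjusted p = 4.24e-07; adjusted p = 0.239 with an estimated correlation). Adjusted over the list alone, Pdgfra (-0.38, SE 0.088, 63.5 against 48.8 CPM), Egfr (-0.47) and Tnr (-0.40) passed. Pdgfra is the growth factor receptor that marks these cells. Sox10 was at -1.05 (SE 0.373) with few counts, 0.902 against 0.436 CPM. Microglia and macrophage genes were lower in 29 of 33 cases, with a median of -0.18 (camera adjusted p = 5.5e-05; adjusted p = 0.239 with an estimated correlation): the macrophage receptor Mrc1 (-0.44, SE 0.114), F13a1 (-0.64) and the complement genes C1qc (-0.41) and C1qb (-0.41); without heterozygote replicate 2 the median was -0.29. Of 24 pericyte and mural cell genes 18 were lower, with a median of -0.13 (camera adjusted p = 0.0214; adjusted p = 0.299 with an estimated correlation), among them Gucy1b1 (-0.38), Acta2 (-0.49), Cspg4 (-0.29, and -0.38 to -0.15 with 1 library left out) and Tbx18 (-0.30, and -0.40 to -0.16). The pericyte median was -0.21 without wt replicate 2, and the call was lost without wt replicate 3 (-0.069) and in the 4 other libraries alone (-0.068). Of 20 erythroid genes 13 were lower, with a median of -0.23 (camera adjusted p = 0.00243; adjusted p = 0.343 with an estimated correlation), a call lost without wt replicate 1 (-0.15). Adjusted over the list alone 2 passed, 1 higher and 1 lower, the higher being the embryonic globin Hbb-y (2.62, SE 0.533, and 1.695 without heterozygote replicate 3); Slc25a37 (-0.37) and the adult globin Hbb-bt (-0.55) were lower. Over all genes 0 members of the precursor, microglia, pericyte and erythroid lists passed edgeR's test, and DESeq2 called none. At an unadjusted p under 0.05 were 7, 7, 2 and 7, of which 1 microglial and 1 erythroid gene were higher. In the microglia and pericyte lists 0 passed adjusted over the list alone. Endothelial genes were lower in 19 of 35 cases, with a median of -0.01 (camera adjusted p = 0.545), Itm2a (-0.26) and the receptor Tek (-0.20) having the lowest p.

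Lists of the midbrain and hindbrain, the thalamus, and the cortical hem and hippocampal primordium were called higher. Of 10 midbrain and hindbrain genes 9 were higher, with a median log2 fold change of 0.25 (camera adjusted p = 0.0237; adjusted p = 0.464 with an estimated correlation). These had low counts: Tal2 (0.74, SE 0.31; 0.952 against 1.62 CPM), Pax3 (0.48), Foxa2 (0.64) and Tal1 (0.27). With 1 library left out these ran from 0.42 to 0.96 for Tal2, 0.30 to 0.60 for Pax3, 0.37 to 1.07 for Foxa2 and 0.16 to 0.43 for Tal1. Midbrain and hindbrain scores differed by 0.60 within the pair of libraries and 0.10 within the 4 others, thalamic scores by 0.13 in either, and hem scores by 0.038 and 0.13. The midbrain and hindbrain call was lost without wt replicate 3 (0.038) or heterozygote replicate 3 (0.22). It was also lost by DESeq2 (0.25), with no low-count filter (0.19) and in the 4 other libraries (0.068). Without heterozygote replicate 1 the midbrain and hindbrain median was 0.42. Of 23 thalamic genes 16 were higher, with a median of 0.14 (camera adjusted p = 0.0358; adjusted p = 0.464 with an estimated correlation). Shox2 (0.83, SE 0.19, 5.46 against 9.74 CPM) passed adjusted over the list alone. Barhl2 (0.58) and Irx1 (0.40) were higher, and the serotonin transporter Slc6a4 was lower with few counts (-0.88, 0.767 against 0.412 CPM). The thalamic call was lost without wt replicate 2 (0.19), wt replicate 3 (0.20) or heterozygote replicate 3 (0.055), by limma-voom (0.15), in the 4 other libraries (0.19) and in thinned counts (0.11). Of 22 genes of the cortical hem and hippocampal primordium 16 were higher, with a median of 0.15 (camera adjusted p = 0.0323; adjusted p = 0.36 with an estimated correlation): Dmrt3 (0.53, SE 0.174), Wnt8b (0.48), Lmx1a (0.26) and Dmrta2 (0.46, and 0.24 to 0.62 with 1 library left out). The hem call was lost without wt replicate 1 (0.13), wt replicate 3 (0.15) or heterozygote replicate 3 (0.064), and in thinned counts (0.12). None of the midbrain or hem genes passed edgeR adjusted over the list alone, and over all genes 0 members of the 3 lists passed. At an unadjusted p under 0.05 were 1, 5 and 1, the 5 thalamic genes being 3 higher and 2 lower. DESeq2 called Shox2.

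Kinase, splicing, ribosomal and p53 lists were called higher and the sterol list lower. Of 16 DYRK, CLK and HIPK kinases and partners, a list without Dyrk1a, 13 were higher, with a median log2 fold change of 0.068 (camera adjusted p = 0.00496; adjusted p = 0.239 with an estimated correlation). The paralog Dyrk1b (0.34, SE 0.091; 44.1 against 55.8 CPM), the binding partner Dcaf7 (0.23) and the splicing kinases Clk1 (0.17) and Clk2 (0.18, and 0.12 to 0.24 with 1 library left out) had the lowest p, and the median was 0.12 without heterozygote replicate 1 and 0.028 without heterozygote replicate 3. Of 47 SR proteins and splicing regulators 38 were higher, with a median of 0.096 (camera adjusted p = 0.0161; adjusted p = 0.53 with an estimated correlation), a call lost without wt replicate 3 (0.039) or heterozygote replicate 3 (0.025). Srsf5 (0.20) and Srsf6 (0.24) were higher, and the neural splicing factors Khdrbs2 (-0.21) and Nova2 (-0.20) lower. With 1 library left out, Srsf6 ran from 0.15 to 0.34 and Nova2 from -0.27 to -0.13. Of 84 cytosolic ribosomal proteins 65 were higher, with a median of 0.069 (camera adjusted p = 0.00365; adjusted p = 0.696 with an estimated correlation), among them Rpl7l1 (0.21), Rpl26 (0.21), Rps3a1 (0.23) and Rpl7 (0.17). With 1 library left out Rpl26 ran from 0.072 to 0.29, Rps3a1 from 0.10 to 0.30 and Rpl7 from 0.12 to 0.27. Ribosomal scores differed by -0.004 within the pair of libraries and 0.11 within the 4 others, and kinase scores by 0.092 and 0.11. Splicing scores differed by 0.067 and 0.064, sterol scores by -0.03 and -0.11, and p53 scores by 0.082 and 0.094. Without wt replicate 1 or heterozygote replicate 2 the ribosomal median turned to -0.015 and -0.009 with no call. It was 0.032 with no call without wt replicate 2, 0.19 without wt replicate 3 and 0.12 without heterozygote replicate 3. Of 29 cholesterol synthesis genes 23 were lower, with a median of -0.076 (camera adjusted p = 0.0184; adjusted p = 0.434 with an estimated correlation), among them Dhcr7 (-0.21), Hmgcs1 (-0.24, and -0.32 to -0.15 with 1 library left out) and Sqle (-0.15). The sterol call was lost without wt replicate 1 (-0.051) or heterozygote replicate 2 (-0.071), and the median was -0.12 without wt replicate 3. Of 25 p53 targets 14 were higher, with a median of 0.037 (camera adjusted p = 0.0358; adjusted p = 0.239 with an estimated correlation). Sesn2 passed adjusted over the list alone, ahead of Psrc1 (0.39), Trp53inp1 (0.53) and Sesn1 (0.15). The p53 call was lost without wt replicate 1 (0.009), wt replicate 3 (0.041), heterozygote replicate 2 (0.049) or heterozygote replicate 3 (0.037), by limma-voom (0.06), with no low-count filter (0.024), with length and GC trends removed (0.029) and in thinned counts (0.02), and without wt replicate 2 the median was 0.067. In the kinase, splicing, ribosomal and sterol lists 0 members passed adjusted over the list alone. Over all genes 0 members of the 5 lists passed edgeR's test, and DESeq2 called Sesn2. At an unadjusted p under 0.05 were 3, 3, 1, 2 and 3, against 1528 of all 19403 tested genes. Of the 3 splicing genes 1 was higher and 2 were lower.

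Lists of other cell types and pathways did not pass the camera test. Of 29 interferon genes 18 were lower (median -0.092, camera adjusted p = 0.0978). Tap1 (1.04), Rsad2 (-1.47) and Ifi27 (-1.15) passed edgeR adjusted over the list alone. Counts were low, with Tap1 at 1.99 against 4.11 CPM, Rsad2 at 1.26 against 0.457 and Ifi27 at 1.67 against 0.74. The interferon list was called without wt replicate 1 (-0.11) or heterozygote replicate 1 (-0.19) and with replicate number as a block (-0.086). Choroid plexus genes had a median of -0.066 (camera adjusted p = 0.131) and were called without wt replicate 1 (-0.092) or heterozygote replicate 1 (-0.09). Among them were Prlr (-0.48) and F5 (-1.18, and -1.82 to -0.91 with 1 library left out). F5 had few counts (1.15 against 0.499 CPM). Mitochondrially encoded genes had a median of -0.17 (camera adjusted p = 0.137), with mt-Rnr1 (-1.12, and -1.72 to -0.26 with 1 library left out) and mt-Nd6 (-0.64, and -1.003 to -0.18), and were called without wt replicate 3 (-0.35) or heterozygote replicate 3 (-0.27), with a term for the pair of libraries (-0.16) and in the 4 others alone (-0.14). Hypothalamic genes, with Rax (0.91, 0.446 against 0.828 CPM) and Pomc (0.56), had a median of 0.17 (camera adjusted p = 0.15). That list was called in the 4 other libraries alone (0.23). Hypoxia and glycolysis genes had a median of -0.015 (camera adjusted p = 0.184) and were called without wt replicate 1 (-0.068) or heterozygote replicate 2 (-0.089); Egln3 (-0.73) passed adjusted over the list alone, and Slc2a3 was at -0.22. The 81 nuclear-encoded genes of oxidative phosphorylation had a median of 0.003 (camera adjusted p = 0.785). The lowest p values were those of Cox7a1 (1.12, with few counts, 0.412 against 0.901 CPM) and Atp5g3 (-0.15). That list was called lower without wt replicate 1 (-0.068) and higher without wt replicate 3 (0.10) or heterozygote replicate 3 (0.047).

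Further lists that did not pass include axon guidance, with a median log2 fold change of -0.017 (camera adjusted p = 0.15) and the lowest p in Sema3c (-0.41) and Epha6 (-0.45). Heat shock genes had 0.044 (camera adjusted p = 0.153), with Dnajb1 (0.16) and Stip1 (0.16, and 0.082 to 0.23 with 1 library left out), and canonical Wnt targets 0.051 (camera adjusted p = 0.326), with Nkd1 (0.34) and Lgr6 (-0.55); without heterozygote replicate 3 the Wnt median was -0.043. Immediate early genes had 0.078 (camera adjusted p = 0.392), with Btg2 (0.36) and Ier2 (0.49), and NFAT and calcineurin genes -0.034 (camera adjusted p = 0.551), with Nfatc4 (0.31) and Rcan3 (-0.15, and -0.20 to -0.083 with 1 library left out). Cajal-Retzius genes had 0.12 (camera adjusted p = 0.564), with Nhlh2 (0.35) and Spock1 (-0.26). Integrated stress response genes had a median of 0.038, a mean of -0.009 and a camera statistic on the higher side (camera adjusted p = 0.549); Sesn2 and Ddit4 (0.46) passed edgeR adjusted over the list alone. Interneuron genes had a median of 0.021, a mean of -0.002 and a camera statistic on the lower side (camera adjusted p = 0.747), with Sst (-0.48) and Npy (-0.45) the lowest in p. With 1 library left out, medians ran from -0.12 to -0.053 for choroid plexus, 0.056 to 0.14 for Cajal-Retzius cells and -0.19 to -0.054 for interferon. They ran from 0.093 to 0.21 for hypothalamus, -0.044 to -0.008 for axon guidance and 0.024 to 0.077 for heat shock. Scores of 8 uncalled lists differed in opposite directions within the pair of libraries and within the 4 others: hypothalamus (-0.075 and 0.17), Wnt (-0.075 and 0.054), heat shock (-0.027 and 0.062), immediate early (0.092 and -0.003), endothelial (-0.037 and 0.009), integrated stress (0.027 and -0.023), oxidative phosphorylation (-0.06 and 0.049) and chromosome 16 neighbours (0.01 and -0.029). In the uncalled lists other than interferon, hypoxia and integrated stress response, 0 members passed edgeR adjusted over the list alone.

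Camera with a preset correlation of 0.01 called 26 of 42 lists, 16 higher and 10 lower. With an estimated correlation 0 of the calls held, with 4 lists at an unadjusted p under 0.05, and fry called 0, with 13 at an unadjusted p under 0.05. In 20 of all 42 lists, 17 called and 3 uncalled, the 3 heterozygote scores lay all above or all below the 3 wt scores; chance gives 10% for a single list, and lists scored on the same libraries are not independent. Scores of 25 of the 26 differed in the same direction within the pair of libraries and within the 4 others, the ribosomal list being the exception. Among the called lists, genotypes overlapped in the erythroid, ribosomal, midbrain and hindbrain, histone, splicing, hedgehog, thalamic, Notch and apical scores. Exact permutation p values over these scores were 0.7 for erythroid, 0.6 for ribosomal and 0.5 for midbrain and hindbrain genes. They were 0.4 for histone, splicing, hedgehog and thalamic genes, and 0.2 for Notch and apical genes. Calls of 11 of the 26 lists held in every leave-one-out fit. The list of X-inactivation and Y-linked genes, a check of sex left out of the count, had 5 tested members and a median of 0.049.

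**Figure D3:**
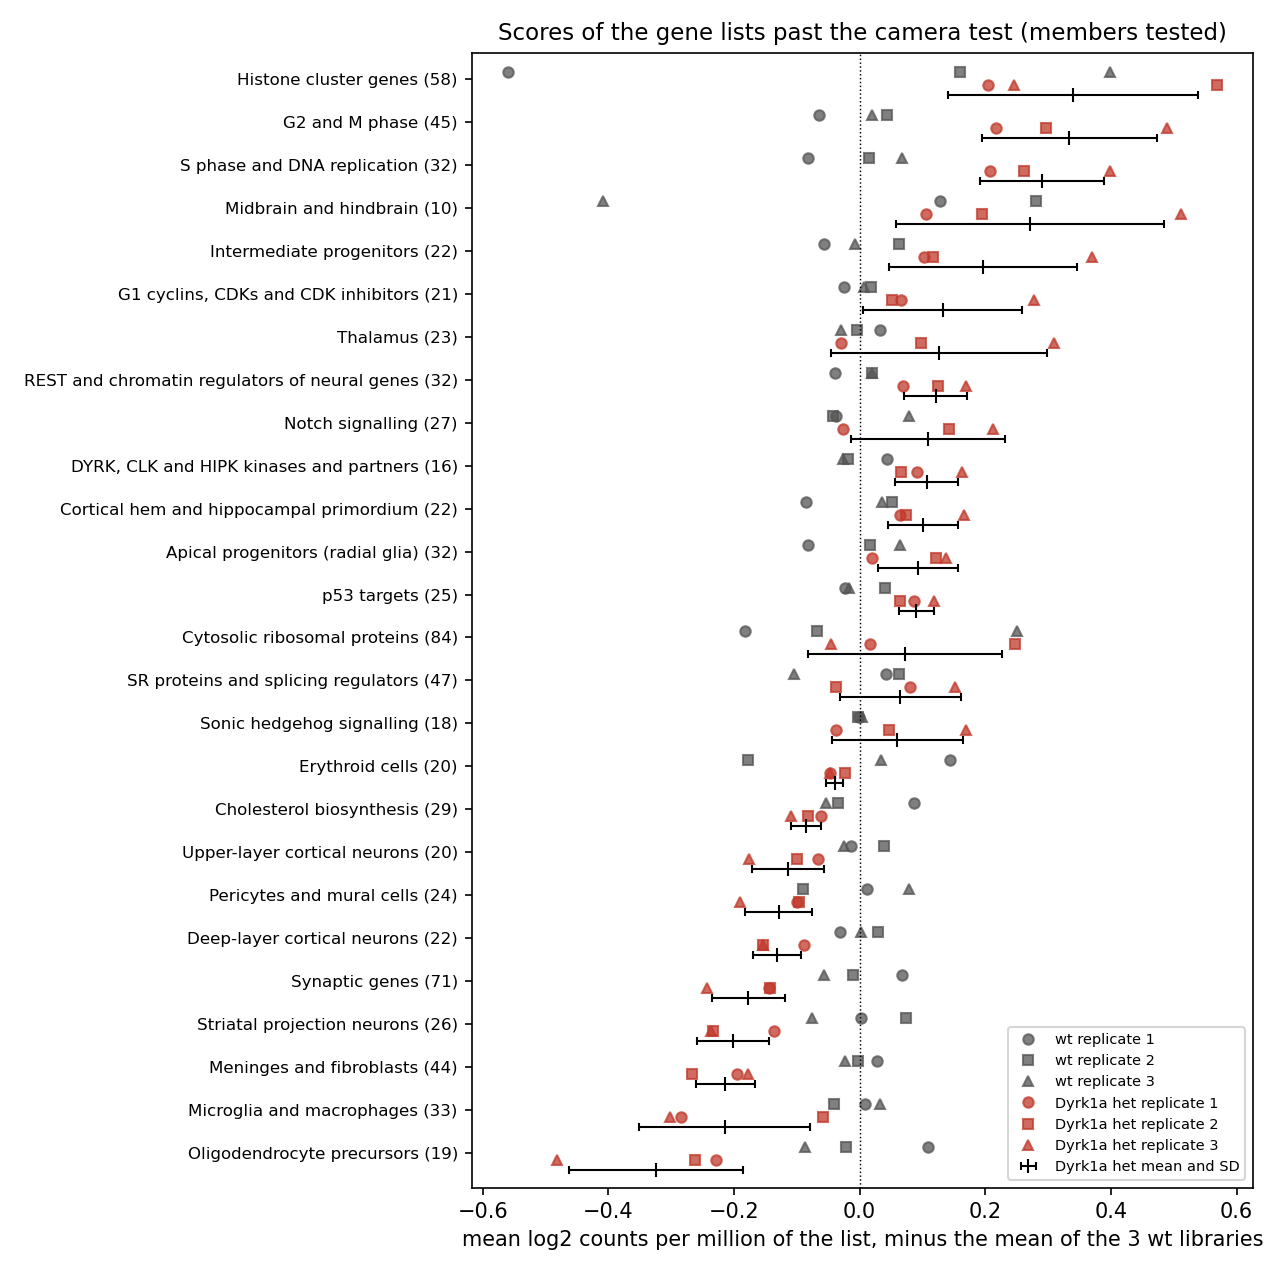
Scores of the 26 called lists in each library: the mean log2 CPM of a list's tested members minus the mean of the 3 wt libraries, with the mean and SD of the 3 heterozygotes as a bar. In the G2 and M list the heterozygotes lie at 0.22, 0.30 and 0.49 and the wt libraries between -0.064 and 0.044. The genotypes overlap in the histone, erythroid, ribosomal, midbrain and hindbrain, splicing, hedgehog, thalamic, Notch and apical lists.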

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

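The term for the pair of libraries with the most 7SK, RNase P and RNase MRP RNA, the 4 other libraries alone, thinned counts and the removal of length and GC trends were tests chosen only after the data were seen. Of the gene values over all settings 2936 kept their direction and side of the threshold, 10 lost a call, 17 gained one and 16 changed sign. Of the list values 713 kept camera's direction and side of the threshold, 95 lost a call, 14 gained one and 18 turned in camera's direction; medians changed sign in 24 of 840, 17 of them with 1 library left out. The count of 2 genes became 27 with DESeq2, 4 with no low-count filter, 6 with the term for the pair of libraries and 6 in the 4 other libraries; the cause was not tested. Pairing by replicate number was not seen in correlations of same-numbered libraries after genotype means were removed (0.201, -0.325 and -0.165). The closest match was wt replicate 3 with heterozygote replicate 2 (0.452). That pair's difference from the 4 other libraries weighs on all these values, so they cannot exclude pairing by replicate number. With replicate number as a block 0 genes passed edgeR (1110 at an unadjusted p under 0.05; 27 genes by DESeq2 without the block), with fewer residual degrees of freedom, and 27 lists passed camera. The count of 26 lists became 0 with an estimated correlation and 0 with fry, which make other assumptions about correlation. Dyrk1a stayed lower in each setting, from -0.26 to -0.16, and never passed.

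Of 178 genes followed, 54 moved over 1.5 times or changed sign with 1 library left out, 0 of them among the 2 called. Without 1 library the gene count ran from 0 to 5, with fewer samples in each fit. The direction of some values turned in leave-one-out fits, with log2 fold changes from -0.044 to 0.059 for Vps26c, -0.034 to 0.049 for Ttc3, -0.47 to 0.24 for Xist, -0.28 to 0.027 for mt-Cytb, -0.083 to 0.30 for Uty and -0.062 to 0.17 for Ddx3y. Where camera's direction turned, list medians ran from -0.05 to 0.13 for immediate early genes, -0.015 to 0.19 for ribosomal proteins, -0.068 to 0.10 for oxidative phosphorylation, -0.043 to 0.079 for interneurons, -0.051 to 0.06 for the integrated stress response, -0.086 to 0.029 for endothelial cells, -0.089 to 0.068 for hypoxia, -0.11 to 0.003 for NFAT, -0.35 to -0.005 for mitochondrially encoded genes and -0.029 to 0 for chromosome 16 neighbours, the last pair with no median of the other sign; that of canonical Wnt targets ran from -0.043 to 0.082; the cause was not tested. Other changes of sign were Vps26c (-0.001) and oxidative phosphorylation (-0.009) with no low-count filter, oxidative phosphorylation (-0.017) and endothelial cells (0.01) with length and GC trends removed, Ttc3 (-0.007), Xist (0.068), endothelial cells (0.029) and chromosome 16 neighbours (0.008) in the 4 other libraries, and chromosome 16 neighbours (0.01) and oxidative phosphorylation (-0.007) in thinned counts. The planned term for Y-linked expression was not run, since all 6 libraries expressed these genes, and the robust fit gives no list values because camera does not use it. With 200 genes changed in the simulation, 30% of 1.5-fold and 70% of 2-fold changes were called. The adjusted threshold loosens as more genes change, and 2 genes passed in the real comparison, so those shares do not carry over to it. Genes beyond 2-fold also missed the threshold, such as Dio2 (log2 fold change -1.22, edgeR, Benjamini-Hochberg adjusted p = 0.189).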

Other observations

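The test of a lower share of all non-neural cells and the test of Ptgds against other meningeal genes were chosen only after the result was seen, and the single genes named in this part were picked after their values were seen. Haemoglobin genes of the embryonic and adult kinds went opposite ways. Embryonic Hbb-y was at 4.49, 6.54 and 9.53 CPM in wt and 21.5, 22.8 and 82.5 CPM in heterozygotes, a log2 fold change of 2.62 (SE 0.533; 1.695 without heterozygote replicate 3) that did not pass edgeR's test (Benjamini-Hochberg adjusted p = 0.483), and embryonic Hba-x was at 1.21 (SE 0.54). Hba-x had few counts (0.979 against 2.28 CPM), and its genotypes overlapped. All 4 adult globin genes were lower, with a median log2 fold change of -0.48, Hbb-bs being at 490.0 CPM in wt and 386 in heterozygotes. Neither Hba-x nor any adult globin passed edgeR's test over all genes (Benjamini-Hochberg adjusted p of 0.529 to 0.754).

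Further single genes that missed edgeR's threshold were lower, with no list tested for them. These were the serotonin receptors Htr1a (log2 fold change -1.29, SE 0.246) and Htr7 (-0.87, SE 0.188), the neurotensin receptor Ntsr1 (-0.67, SE 0.133), which marks deep-layer neurons, and the receptor subunit Neto1 (-0.61, SE 0.123); DESeq2 called Htr1a, Ntsr1 and Neto1. The astrocyte water channel Aqp4 was also lower (-1.06, SE 0.22; 1.92 against 0.92 CPM). The cell cycle genes Spag5 (0.37, SE 0.072) and E2f8 (0.58, SE 0.122) were higher.

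The first pattern weighed was higher cell cycle lists with a lower synaptic list in heterozygotes. A single library and a gene length or GC trend are argued against as the whole cause: the G2 and M median stayed at 0.259 or above with any library left out, and was 0.351 once length and GC trends were removed. An earlier developmental stage of the heterozygote forebrains was tested on early heterochronic genes such as Igf2bp1, Hmga2 and Lin28b, of which 18 of 20 were higher, with a median of 0.117 (camera p = 0.000446 unadjusted; p = 0.11 with an estimated correlation). Among the 20, Imp3 (0.03) is a different gene that shares an alias with the member Igf2bp3, and is not itself an early heterochronic gene. Of these 20 genes, 2 were at an unadjusted p under 0.05 by edgeR. Hmga2 (0.31, edgeR unadjusted p = 0.135) and Lin28b (0.076, edgeR unadjusted p = 0.516) were not. The heterozygote scores were 0.084, 0.083 and 0.249, the highest in replicate 3, and the member E2f5 is also in the G1 list. An earlier stage at collection may account for the pattern, but these genes are also expressed in progenitors. An earlier stage cannot be separated here from a larger progenitor share or from slower development in the mutant. The real grouping called 26 lists, 1 of 10 splits of the 6 libraries (itself) called as many, and the highest other called 19; 10 splits cannot give a share under 0.05.

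The second pattern was the lower meninges and fibroblast list. Less meningeal tissue in the heterozygote samples stays open: 10 of the 10 members of highest CPM were lower, which mostly restates that 38 of 44 were, and they ran from Col6a3 (-0.49, 74.6 against 52.99 CPM) and Col1a2 (-0.32) to Sparc (-0.058) and Lama1 (-0.019); 1 of the 44 members is in another fixed list. A lower share of all non-neural cells is open as well. The endothelial median lay 0.154 above the meninges median (SE 0.063, taken over genes as if independent, not over embryos). It lay 0.171 to 0.187 above, beyond 2 such SE, without wt replicate 3, heterozygote replicate 1 or heterozygote replicate 3. The difference was 0.07 (SE 0.071) without wt replicate 1, 0.117 (SE 0.064) without wt replicate 2 and 0.034 (SE 0.069) without heterozygote replicate 2. The microglia (-0.18) and pericyte (-0.13) medians were as low or nearly so. Ptgds lay below the median of the other 43 members (difference -1.004, SE 0.116), more than a smaller share of meningeal tissue with its genes in constant proportion gives. Ptgds was picked as the lowest of the 44, and the lowest of the others was at -0.873. The SE covers Ptgds and the median, the latter over genes as if independent, and not the spread between members. How much tissue each dissection held is not in the labels, and a genotype effect on the meninges was not tested.

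The third pattern, in genes picked after their values were seen, was higher values of Trp53inp1, Sesn2, Sesn3, Ddit4, Pik3r3, Mxd4, Pdcd4 and Ypel2, with log2 fold changes of 0.36 to 0.86 and 0 of 8 past edgeR's threshold over all genes (8 of 8 at an unadjusted p under 0.05, which the choice largely fixed; DESeq2 called Sesn2, Pik3r3, Mxd4 and Ypel2, and edgeR with a term for the pair of libraries rich in 7SK called Trp53inp1 and Mxd4). Higher FOXO activity might raise them. In a list of 31 other FOXO-regulated genes, Foxo1, Foxo3, Foxo4 and Foxo6 among them, the median was 0.007 (SE 0.05, over genes as if independent). The exact permutation p over the list score was 0.2. The bound set in advance counted a median that low against FOXO activity. Of the 31, 16 were higher, and camera gave an unadjusted p of 0.83 (0.847 with an estimated correlation). With members so evenly split, the test was scored as unable to decide on FOXO activity. These values argue against a rise shared across these 31 genes. A rise limited to some FOXO targets was not tested. No technical explanation was tested for this pattern.

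Of the 10 splits of the 6 libraries 4, the real one included, called as many genes as the 2 of the genotype comparison. The highest other called 12, with wt replicates 1 and 2 and heterozygote replicate 1 on 1 side, several times the real count, which points to a structure of the samples other than genotype. The 4 splits that put wt replicate 3 and heterozygote replicate 2, the pair rich in 7SK, on the same side called 12, 5, 3 and 0 genes. With a term for that pair 6 genes passed between genotypes, the original 2 among them. With 10 splits no share under 0.05 can be reached.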
